A study of Mus musculus with 24 samples.

How the data were processed

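RNA from mouse embryonic stem cells of the CCE line was measured on 24 Illumina bead arrays, on which each probe is carried by many beads and read as a fluorescence intensity. The labels give 8 groups of 3 arrays. Cells labelled wild type and cells labelled knockout each received ethanol, the vehicle, or all-trans retinoic acid for 1, 8 or 24 h. The ethanol arrays carry the time 0 h and served as the control for all 3 times of their own genotype. No ethanol arrays are labelled 1, 8 or 24 h. Changes with time alone and changes with retinoic acid can therefore not be told apart, and both are included in what is called the response. The series text names the knocked-out gene as the retinoic acid receptor gamma gene, Rarg, whereas the sample labels write the genotype as RARE_KO, which does not spell out the gene. The samples are therefore called arrays or cells labelled knockout throughout.

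Per the labels' protocols, RNA was extracted with Trizol, checked on a Bioanalyzer and amplified and biotin-labelled with a TotalPrep kit. The deposited intensity of each probe is a mean over its beads that was not normalized between arrays, exported with BeadStudio 3.1.7, per the file headers. The deposited detection p-value of each probe compares it with the negative-control beads of the same array, per the file headers. The deposited number of beads per probe is a count and was used only to describe the arrays. The authors' value table of the series holds log2 values whose scale no label states. Set against the deposited intensities, it equalled the quantile-normalized log2 intensity centred on each probe's median over the arrays, with a largest absolute difference of 0.00513, so its scale, centring and direction were known. Analysis started from the non-normalized intensities. Background was corrected by normexp with the negative-control level inferred from the detection p-values, arrays were quantile-normalized, and log2 was taken with an offset of 16 (neqc in limma 3.58.1, R 4.3.3). Fold changes of dim genes are therefore compressed toward 0, and quantile normalization assumes that most genes do not shift in 1 direction.

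Of 25697 probes, 14268 had a detection p under 0.05 on at least 3 arrays and were kept. Probes were named through a gene table of the mouse assembly GRCm38.p6, 16938 by Entrez ID and 7420 by accession, and 1339 kept the symbol of the file. The symbol was updated for 7344 probes. For each gene the probe with the highest mean over the 24 arrays was tested, which gave 10432 genes, 7730 of them with 1 kept probe and 2702 with several. The labels and deposited files name no genome build, so no positions are given. A gene not detected on any of the 3 arrays of a group has only a bound there: its change is written as at least N-fold, the mean of the brighter group against the mean of the lowest detected signal on each dim array, or the probe's own signal where that was higher.

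A linear model with 1 mean per group was fitted to all 24 arrays with limma (lmFit and eBayes), leaving 16 residual degrees of freedom and adding 4.21 from the prior. The model was used for 10 comparisons: retinoic acid against ethanol at each of 3 times in each genotype, knockout against wild type under ethanol, and the difference between the genotypes in the response at each time (the interaction). Every p-value was two-sided and adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Only the second probe of Rarg was adjusted over all probes instead. The errors given are standard errors of the log2 fold change from this fit, with n = 3 arrays per group. The number of arrays limits the precision: with 3 against 3 the smallest exact two-sided p is 0.1. The labels do not say that replicates are separate cultures, so p-values measure only the spread between these samples, which can be technical.

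Gene lists were tested against all other genes with camera in limma at its preset correlation of 0.01, adjusted over 220 tests (22 lists in 10 comparisons), and again with a correlation estimated from the data. Of the 220 tests, 61 passed at the preset correlation, and the estimated value is given for each that was lost. For lists that kept their call it could still be far larger than the preset value printed. Hox paralogs 1 to 5 in wild-type cells at 1 h had an adjusted p of 4.69e-05 in place of 6.04e-20. Counts of list members are given over all genes tested and, where they differ, adjusted over the list alone. The lists were retinoid metabolism and transport, retinoid receptors and corepressors, Hox paralogs 1 to 5, Hox paralogs 6 to 13, TALE and Cdx Hox cofactors, pluripotency, formative and primed state, primitive and parietal or visceral endoderm, primitive streak and mesoderm, neural, trophoblast, fibroblast (feeder) markers, germ cell and meiosis, 2-cell-like (Zscan4) genes, Polycomb repressive complexes, DNA methylation machinery, immediate early genes, FGF-ERK response genes, Wnt and BMP response genes, cell cycle, p53 and apoptosis, and stress and unfolded protein response.

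The groups, lists, comparisons, tests and the rule for naming genes were fixed before the data were examined. The rule names Rarg, and in each comparison the genes past the threshold with the largest rises and falls whose groups of 3 did not overlap, an outcome with an exact two-sided p of 0.1 for any 1 gene. For interactions the sign had to be kept when each array was left out. It takes 10 in each direction for wild-type cells at 8 and 24 h and for the interaction at 24 h, and 5 in each direction elsewhere, plus at most 4 members of each list with the smallest p. Provisional gene names were counted but not named. A gene named in 1 comparison could be followed in the others. Some genes that the rule names are not reported here, in the text or the plots, and they are still included in the counts and the list tests.

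Simulated data with 200 of 10432 genes changed by a known amount were fitted with the same linear model. Log2 values were drawn independently around each gene's mean, with the same spread on every array. Background correction, normalization, the detection filter, the choice of probes and differences in quality between arrays were therefore not tested. For wild-type cells at 24 h, 12.5% of genes changed by a log2 of 0.5 were recovered, 89.5% of those changed by 1 and 99.5% of those changed by 2. For the interaction at 24 h the shares were 0.5%, 59.5% and 98%. Among the genes left unchanged there were 2, 12 and 18 false calls for wild-type cells at 24 h and 1, 3 and 10 for the interaction. Beside the 25, 179 and 199 genes recovered for wild-type cells, and beside the 1 recovered at a log2 of 0.5 for the interaction, these are above the 5% of calls that the threshold allows on average. No changed gene was called with the wrong sign, and data without any change gave 0 calls in all 10 comparisons.

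The counts of genes, the list tests that passed, the genes named by the rule and the overlap of the lines at 24 h were recomputed with no background correction, with the authors' value table, with median scaling in place of quantile normalization, with no filter or a stricter filter on detection, with all probes, with only the groups compared, with the replicate number as a block, with array weights, and without each array in turn. Without the 2 dimmest arrays and with array brightness as a covariate were added after seeing the data, as were the alternatives for the overlap and for the imprinted genes and share of the response under other observations. The stricter filter leaves out the genes of 10 named results. The authors' value table differs from no background correction only by centring, so they are the same alternative.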

Results

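Transcript levels were measured in CCE cells, a line of mouse embryonic stem cells that self-renews in culture and leaves the pluripotent state when exposed to retinoic acid, the active derivative of vitamin A that switches on genes through nuclear retinoic acid receptors. Cells labelled wild type and cells labelled knockout were compared after ethanol or after retinoic acid for 1, 8 and 24 h, with 3 arrays in each of 8 groups. The question posed by the series was how the response to retinoic acid differs in cells that lack the receptor gene Rarg. The mean raw intensity ran from 231.6 on wild-type 8 h replicate 2 to 1695.5 on wild-type 8 h replicate 3, and 47.9% to 50.7% of probes were detected on each array. The mean correlation with the other arrays of the same group lay between 0.9759 and 0.9964, across probes within samples, and 0 arrays were identical. The first principal component carried 37.7% of the variance and placed the arrays labelled wild type and knockout on opposite sides. It was followed by a component with 21% along which the arrays spread with time in retinoic acid.

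Rarg, the receptor gene named in the series, was lower but present on the arrays labelled knockout. Its probe ILMN_2618068 read 10.57 ± 0.07 (log2 intensity, mean and SD, n = 3) under ethanol in wild-type cells and 10.06 ± 0.14 in cells labelled knockout, and was detected on all 24 arrays. The difference was -0.51 ± 0.12 (log2, SE, n = 3 per group) with an adjusted p of 0.00399. In wild-type cells Rarg read 10.75 ± 0.16 after 1 h of retinoic acid, 10.38 ± 0.21 after 8 h and 9.83 ± 0.06 after 24 h, and the fall at 24 h was -0.74 ± 0.12 (adjusted p = 0.000143). In cells labelled knockout it read 10.33 ± 0.21, 10.49 ± 0.09 and 10.16 ± 0.14 at the same times. A second probe, ILMN_3132660, differed by -0.24 ± 0.09 under ethanol and changed by -0.49 ± 0.09 at 24 h in wild-type cells. Its p-values were adjusted over all 25697 probes. The difference under ethanol did not pass (adjusted p = 0.101), where ILMN_2618068 had 0.00534 in the same fit. The change at 24 h passed (adjusted p = 0.000859). Another probe was detected on 1 array. The position of the probes relative to any deleted part was not known here, so the signal does not check the label. With median scaling the difference under ethanol was -0.26 with an adjusted p of 0.593, and the fall at 24 h in wild-type cells also lost its call.

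**Figure D1:**
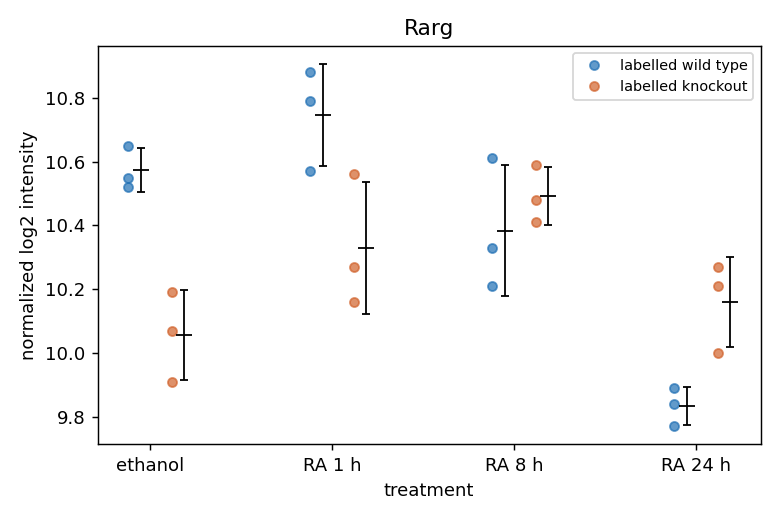
Normalized log2 intensity of Rarg on each array (points) after ethanol and after retinoic acid for 1, 8 and 24 h, with the mean and SD of the 3 arrays, blue for arrays labelled wild type and orange for arrays labelled knockout. The 8 group means lie between 9.83 and 10.75.

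Within 1 h, wild-type cells raised the anterior Hox genes, which set position along the head-to-tail axis of the embryo, together with retinoic acid receptor genes. Hoxa5 rose by 1.70 ± 0.21, Hoxb4 by 1.62 ± 0.22 and Hoxb5 by 1.60 ± 0.21 (log2, SE, n = 3 per group, adjusted p between 7.79e-05 and 0.000248). Rarb, itself a receptor gene and a classical direct target of retinoic acid, rose by 1.63 ± 0.18 (adjusted p = 2.22e-05), and Rara by 1.09 ± 0.17 (adjusted p = 0.00138), each detected on 1 of 3 ethanol arrays. The 2 other kept probes of Rarb read 0.19 and 1.25 here, and 0.38 and 2.74 at 8 h. In cells labelled knockout they read 0.03 and 1.12 at 1 h, and 0.47 and 2.44 at 8 h. Otx2, a homeobox gene of the anterior epiblast and forebrain, fell by 1.12 ± 0.16 (adjusted p = 0.000344). In all, 65 genes rose and 7 fell, 24 and 1 of them by 2-fold or more.

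Of 11 measured Hox paralogs 1 to 5, 8 rose and 0 fell (median log2 fold change 1.20, camera adjusted p = 6.04e-20). Of 10 receptors and corepressors, 3 rose (adjusted p = 0.00379), and 1 of the 3, Nrip1, lost its call without each of the 6 arrays compared in turn, at adjusted p of 0.0517 to 0.161. The germ cell and meiosis list also passed (median 0.24, adjusted p = 0.00167), although 1 of its 9 measured members rose, Stra8; the list call was lost at an adjusted p = 0.116 with an estimated correlation. The call of Stra8 was lost without any 1 of the 6 arrays compared except wild-type 1 h replicate 1, at adjusted p of up to 0.136. The formative and primed list, genes of the epiblast about to enter differentiation, moved down by a median of -0.18 (adjusted p = 0.0215), with Otx2 the 1 member that fell among 11. That call was lost at an adjusted p = 0.0557 with an estimated correlation and at 0.0722 without wild-type 1 h replicate 2. Foxa1, a pioneer factor of the endoderm, rose by 1.23 ± 0.18 (detected on 2 of 3 ethanol arrays), Lefty1, an inhibitor of Nodal signalling, by 0.86 ± 0.11, and Tmtc1 by 1.81 ± 0.24 (detected on 1 of 3 ethanol arrays). The other named falls were smaller: Tdrkh, a germline Tudor-domain gene, at -0.68 ± 0.12, Epha1, an ephrin receptor, at -0.71 ± 0.13 (a second probe read 0.28), the water channel gene Aqp11 at -0.74 ± 0.14 and the cell adhesion gene Esam at -0.81 ± 0.15. Esam lost its call without wild-type ethanol replicate 1 (adjusted p = 0.0595), and Aqp11 without that array (0.0816) or without wild-type 1 h replicate 1 (0.0675) or 3 (0.0713). The 72 calls became 47 without wild-type 1 h replicate 1 or 2. With median scaling 10 genes passed, each of them higher, and of the genes named here Rarb, Rara and Tmtc1 kept their calls; fitted on the groups compared alone, 23 passed, without Rara, Tmtc1, Tdrkh, Epha1, Aqp11 and Esam.

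By 8 h the wild-type response had widened to the retinoid-handling genes and to the first losses of pluripotency genes. Hoxb5 rose by 3.44 ± 0.21, Hoxa5 by 3.06 ± 0.21, Hoxb2 by 3.00 ± 0.23, Hoxb4 by 2.89 ± 0.22 and Hoxa4 by 2.67 ± 0.20 (log2, SE, n = 3 per group). Of these, Hoxb2 and Hoxa4 were detected on 2 of 3 ethanol arrays. Hoxb1, not detected under ethanol, was at least 5.69-fold higher (adjusted p = 2.39e-14). Stra8, a gene that germ cells need to enter meiosis, rose by 2.56 ± 0.13 and Rarb by 3.11 ± 0.18. Otx2 fell by 2.07 ± 0.16 (adjusted p = 1.34e-08). There were 621 higher and 402 lower genes, 90 and 39 of them by 2-fold or more.

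Among 11 Hox paralogs 1 to 5, 8 rose (9 up and 1 down adjusted over the list alone; median 2.67, camera adjusted p = 7.64e-17). Of 11 retinoid metabolism genes 3 rose (median 0.16, adjusted p = 0.00609), among them Cyp26a1, which degrades retinoic acid (at least 2.58-fold), and the retinol uptake gene Stra6 (at least 3.16-fold). Of 28 pluripotency genes 9 fell and 0 rose (1 up and 12 down adjusted over the list alone; median -0.21, adjusted p = 0.000328). Tcl1, an Akt coactivator of naive cells, fell by 0.67 ± 0.10 and the threonine dehydrogenase gene Tdh by 0.58 ± 0.11. In the TALE and Cdx list, partners and activators of Hox genes, 6 of 12 rose and Tgif1 fell, with Cdx1 at 1.53 ± 0.13 and Meis2 at 1.16 ± 0.14 (median 0.51, adjusted p = 0.00144, and adjusted p = 0.141 with an estimated correlation). In the germ cell list 3 of 9 rose (5 adjusted over the list alone; median 0.43, adjusted p = 0.000328, and adjusted p = 0.0781 with an estimated correlation), Stra8 and the meiotic cohesin gene Rec8 (0.98 ± 0.11) among them. Dazl, the other member that rose, lost its call without wild-type ethanol replicate 1 (adjusted p = 0.228) or 3 (0.0525) or wild-type 8 h replicate 1 (0.0738) or 3 (0.0811). Of 14 FGF-ERK response genes 4 fell (5 adjusted over the list alone; median -0.25, adjusted p = 0.0179), Spry4, a feedback inhibitor, by 0.94 ± 0.14. That list lost its call with an estimated correlation (adjusted p = 0.0609), without wild-type ethanol replicate 2 (0.0732) and without wild-type 8 h replicate 3 (0.052). Its member Fgf4 lost its call without wild-type ethanol replicate 1 (0.1) or 3 (0.0538) or wild-type 8 h replicate 1 (0.103) or 3 (0.0612).

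Posterior Hox genes had begun to move: of 11 paralogs 6 to 13, Hoxb7 rose by 1.81 ± 0.26, Hoxa7 by 1.33 ± 0.23 and Hoxb6 was at least 1.57-fold higher (list median 0.17, adjusted p = 0.0215). The list call was lost at an adjusted p = 0.265 with an estimated correlation and at 0.139 without wild-type 8 h replicate 3. The other genes with the largest rises were H2-Bl, a class I histocompatibility gene (2.92 ± 0.15), whose near-identical relatives leave the source of its signal uncertain, and the milk protein gene Csn3 (at least 5.31-fold). The other large falls were Zmat4 (-1.69 ± 0.11), the cytochrome Cyp2s1, which is linked to retinoid oxidation (-1.68 ± 0.14), the surface antigen gene Ly6g6e (at least 1.91-fold lower) and the nerve growth factor receptor gene Ngfr (-1.49 ± 0.19). Smaller falls were those of Exoc3l (-1.36 ± 0.20), the FGF carrier gene Fgfbp1 (-1.34 ± 0.23), the keratin gene Krt17 (-1.32 ± 0.18), Ndrg1 (-1.31 ± 0.15) and the fatty acid transporter gene Slc27a2 (-1.27 ± 0.15). The 1023 calls became 546 without wild-type ethanol replicate 1, 151 when the groups compared were fitted alone (without Hoxa7, Tcl1, Tdh and Tgif1), and 109 with median scaling, 85 higher and 24 lower (without Meis2, Rec8, Spry4, Tcl1, Tdh, Tgif1, Fgfbp1 and Slc27a2).

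At 24 h, 2411 of 10432 genes differed from ethanol in wild-type cells, 1349 higher and 1062 lower, and 301 and 175 of these by 2-fold or more. Hox genes were the most raised: Hoxb2 by 5.33 ± 0.23, Hoxb5 by 4.91 ± 0.21, Hoxa5 by 4.34 ± 0.21, Hoxb4 by 4.17 ± 0.22 and Hoxa4 by 4.13 ± 0.20 (log2, SE, n = 3 per group). Hoxb1 was at least 23.3-fold and Hoxb6 at least 7.22-fold higher. Retinoid-handling genes followed, with Stra6 at least 11.8-fold higher and the retinoic acid-binding gene Crabp2 up by 2.79 ± 0.16. Otx2 fell by 3.60 ± 0.16 (adjusted p = 6.19e-13), and pluripotency genes fell as a group. The core factor gene Pou5f1 fell by 0.71 and Nanog fell by 0.38, while Zfp42, a marker of naive cells, fell by 1.26 and Tcl1 fell by 1.98.

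Of 11 Hox paralogs 1 to 5, 9 rose (median 4.13, camera adjusted p = 1.64e-16). Of 11 paralogs 6 to 13, 8 rose (9 adjusted over the list alone; median 1.81, adjusted p = 1.48e-08), including Hoxb7 by 3.21 ± 0.26 and Hoxc9 by 2.32 ± 0.18 (detected on 1 of 3 ethanol arrays). Of 28 pluripotency genes 16 fell and 2 rose (18 and 2 adjusted over the list alone; median -0.53, adjusted p = 1.90e-08). Tdh fell by 2.17 ± 0.11, Fgf4, the main FGF of embryonic stem cells, by 1.66 ± 0.20 and the nuclear receptor gene Nr5a2 by 1.56 ± 0.15, whereas Lefty1 rose by 1.74 ± 0.11. Retinoid metabolism genes rose in 5 of 11 cases (median 0.49, adjusted p = 4.41e-05), with Cyp26a1 at least 5.20-fold higher. The TALE and Cdx list had 7 of 12 up and 1 down (8 and 2 adjusted over the list alone; median 1.12, adjusted p = 5.75e-05), with Cdx1 at 2.46 ± 0.13, Meis2 at 2.33 ± 0.14 and Meis1 at 2.09 ± 0.12. Its call was lost at an adjusted p = 0.0771 with an estimated correlation. With that correlation, Hox paralogs 1 to 5 kept theirs at an adjusted p of 6.17e-05 and paralogs 6 to 13 at 0.0136. Pluripotency kept it at 0.000689 and retinoid metabolism at 0.0031.

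Endoderm genes rose in 8 of 19 cases with 1 fall (10 and 1 adjusted over the list alone; median 0.39, adjusted p = 0.000133). They included Foxa1 (2.68 ± 0.18) and Gata6 (1.44 ± 0.15), a primitive endoderm regulator. Of 14 neural genes 7 rose and 1 fell (8 and 1 adjusted over the list alone; median 0.48, adjusted p = 0.0166), including Zic1 (1.85 ± 0.25, detected on 1 of 3 ethanol arrays) and the spinal progenitor gene Irx3 (at least 2.08-fold). The neural call was lost at an adjusted p = 0.353 with an estimated correlation and with median scaling. The germ cell list had 5 of 9 up (median 0.72, adjusted p = 0.00146, and adjusted p = 0.116 with an estimated correlation), with Stra8 at 3.16 ± 0.13, Rec8 at 1.86 ± 0.11 and Taf7l at 1.29 ± 0.14. Genes with the largest changes outside these groups were the lens crystallin gene Crygc (3.90 ± 0.27, from a family of close relatives) among the rises. The largest falls were those of Exoc3l (-2.64 ± 0.20), the epithelial regulator Grhl2 (-2.47 ± 0.16), Zmat4 (at least 4.05-fold lower) and Enox1 (-2.37 ± 0.13). Others were the immediate early gene Egr4 (at least 3.12-fold lower), Cyp2s1 (-2.12 ± 0.14), the viral RNA sensor gene Ddx58 (-2.11 ± 0.17) and Hmces (-2.11 ± 0.11). With median scaling 1032 genes passed, 840 higher and 192 lower, and the median of all genes was 0.25, so the balance of rises and falls depended on the scaling.

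**Figure D2:**
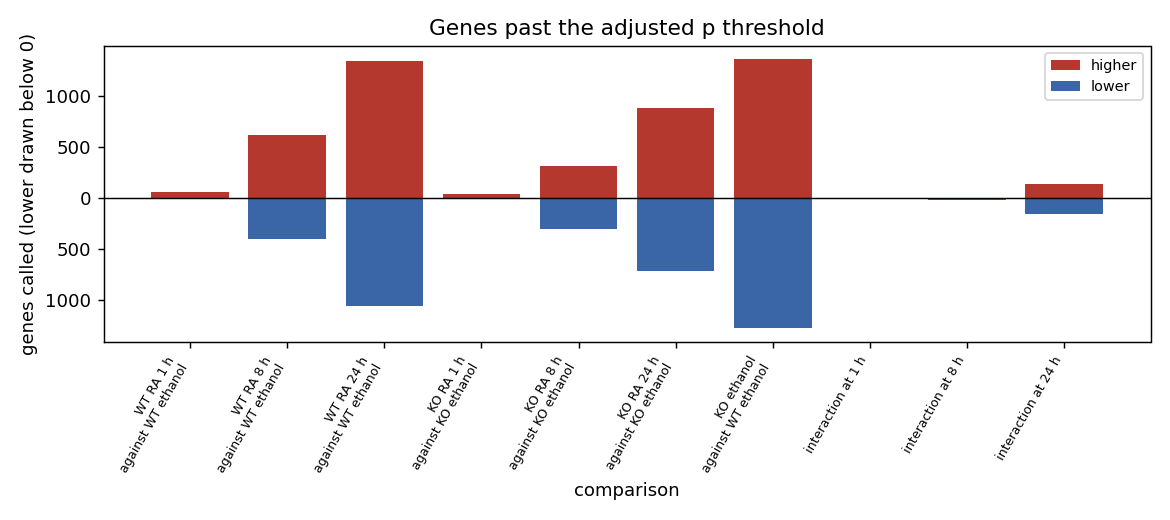
Genes past an adjusted p of 0.05 in each of the 10 comparisons, with genes higher above 0 and genes lower below 0. Counts in wild-type cells grew from 72 at 1 h to 2411 at 24 h and in cells labelled knockout from 43 to 1595, and 2643 genes differed between the lines under ethanol.

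Cells labelled knockout also answered within 1 h, with the same direction for Rarb (1.39 ± 0.18, log2, SE, n = 3 per group) and for Otx2 (-1.59 ± 0.16, adjusted p = 2.32e-05). Hoxb4, not detected under ethanol, was at least 2.29-fold higher, and Tmtc1 rose by 1.60 ± 0.24 and Foxa1 by 1.17 ± 0.18 (each detected on 1 of 3 ethanol arrays). In all, 39 genes rose and 4 fell, 16 and 1 of them by 2-fold or more. The other large rises were the odorant receptor gene Olfr437 (at least 1.66-fold higher) and the TNF receptor family gene Tnfrsf13c (1.35 ± 0.23). The falls were those of the pluripotency regulator Zfp296 (-0.83 ± 0.13), Lrig3 (-0.71 ± 0.12) and Sox21 (-0.59 ± 0.11).

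Of 11 Hox paralogs 1 to 5, 3 rose (4 adjusted over the list alone; median 0.29, camera adjusted p = 2.51e-11). Among the 3, Hoxa5 lost its call without knockout 1 h replicate 2 (adjusted p = 0.054), and Hoxb5 without knockout ethanol replicate 1 (0.0745) or 2 (0.0718) or knockout 1 h replicate 1 (0.0805). The formative list moved down (median -0.18, adjusted p = 0.000333) with Otx2 its 1 called member of 11. Receptors and corepressors passed with 1 of 10 up, Rarb (median 0.10, adjusted p = 0.0258). They lost the call with an estimated correlation (adjusted p = 0.0609), without knockout ethanol replicate 2 (0.113) and without knockout 1 h replicate 3 (0.183). The TALE and Cdx list passed with 1 of 12 up, Cdx1 at 0.86 ± 0.13 (3 adjusted over the list alone; median 0.10, adjusted p = 0.0146). It lost the call at an adjusted p = 0.276 with an estimated correlation and at 0.105 without knockout 1 h replicate 2. Sox21 lost its call without knockout ethanol replicate 1 (adjusted p = 0.0746) or 2 (0.0718) or knockout 1 h replicate 3 (0.0578). The 43 calls became 28 without knockout ethanol replicate 1 and 27 without knockout 1 h replicate 2, and 7 with median scaling, each of them higher (without Otx2, Foxa1, Cdx1, Zfp296, Lrig3 and Sox21). Fitted on the groups compared alone, 10 passed, without Rarb, Foxa1, Olfr437 and the same falling genes except Otx2.

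After 8 h, the cells labelled knockout had raised Hoxa5 at least 4.12-fold and Hoxb4 at least 4.42-fold, with Hoxb5 up by 2.36 ± 0.21 (detected on 2 of 3 ethanol arrays), Rarb by 2.47 ± 0.18 and Cdx1 by 2.37 ± 0.13 (log2, SE, n = 3 per group). Otx2 fell by 2.75 ± 0.16 (adjusted p = 1.96e-10). The histocompatibility genes H2-Bl (2.89 ± 0.15) and H2-T23 (2.46 ± 0.13) rose, with the same doubt about near-identical relatives. Zmat4 (-2.11 ± 0.11), Ddx58 (-2.04 ± 0.17), Grhl2 (-1.98 ± 0.16) and the kallikrein gene Klk1 (at least 3.21-fold lower) fell. In total 318 genes rose and 303 fell, 69 and 43 of them by 2-fold or more.

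Of the Hox paralogs 1 to 5, 6 of 11 rose (8 adjusted over the list alone; median 0.68, camera adjusted p = 2.02e-12). Receptors and corepressors passed with 2 of 10 up (median 0.37, adjusted p = 0.00391), Rarb and Rarg. Rarg rose by 0.43 ± 0.12 with an adjusted p of 0.0407, a call lost without each of the 6 arrays compared except knockout ethanol replicate 1, at adjusted p of up to 0.201, and with median scaling. Pluripotency genes fell in 5 of 28 cases (9 adjusted over the list alone; median -0.12, adjusted p = 0.00391). Among the 5, Klf2 lost its call without any 1 of the 6 arrays except knockout ethanol replicate 2 (adjusted p of up to 0.108), and Lin28a without any except knockout ethanol replicate 1 (up to 0.0995). Formative genes fell in 4 of 11 (median -0.37, adjusted p = 2.29e-06), among them the Wnt effector Lef1 (at least 1.76-fold lower), the de novo methyltransferase gene Dnmt3b (-0.42 ± 0.07) and Pou3f1 (-0.73 ± 0.15). Wnt and BMP response genes fell in 4 of 15 cases with 1 rise (7 and 1 adjusted over the list alone; median -0.32, adjusted p = 0.000697), including Sp5 (-1.04 ± 0.15) and the BMP-responsive gene Id4 (at least 2.33-fold lower). FGF-ERK genes fell in 3 of 14 cases (median -0.21, adjusted p = 0.00783), with Fgf15 at -0.93 ± 0.11. Immediate early genes, which serum and growth factors switch on within minutes, fell in 2 of 14 cases, Fos and Dusp1 (4 adjusted over the list alone; median -0.22, adjusted p = 0.00379). Both lost their calls without knockout ethanol replicate 2 (adjusted p = 0.185 for Fos and 0.0754 for Dusp1) or knockout 8 h replicate 2 (0.15 and 0.0806). Fos also lost it without knockout ethanol replicate 1 (0.0543) or knockout 8 h replicate 3 (0.0818). Stress genes rose in 4 of 13 (6 adjusted over the list alone; median 0.15, adjusted p = 0.00603), led by the heat shock gene Hspa1a (0.86 ± 0.18). The other members that rose were Chac1, Herpud1 and Trib3. Herpud1 and Trib3 lost their calls without each of the 6 arrays compared in turn, at adjusted p of 0.0617 to 0.157 and 0.0797 to 0.121.

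The TALE and Cdx list had 5 of 12 up and 1 down (median 0.38, adjusted p = 6.30e-05, and adjusted p = 0.0781 with an estimated correlation). The germ cell list had 3 of 9 up, with Stra8 at 1.82 ± 0.13 (median 0.13, adjusted p = 0.0149). It lost its call with an estimated correlation (adjusted p = 0.232), with median scaling, and without knockout ethanol replicate 1 (0.0556) or 3 (0.0573) or knockout 8 h replicate 3 (0.0572). Of its 3 members that rose, Smc1b lost its call without knockout ethanol replicate 1 (0.0688) or 3 (0.133) or knockout 8 h replicate 1 (0.0795) or 3 (0.102), and Rec8 without knockout ethanol replicate 1 (0.0658). With median scaling 130 genes passed in place of 621, 89 higher and 41 lower, without Dnmt3b, Pou3f1, Sp5 and Hspa1a.

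After 24 h, 1595 genes differed from ethanol in cells labelled knockout, 882 higher and 713 lower, 205 and 152 of them by 2-fold or more. Hox genes again led: Hoxa5 was at least 18.9-fold and Hoxb4 at least 15.0-fold higher, Hoxb1 at least 6.57-fold. Hoxb5 rose by 4.38 ± 0.21 (detected on 2 of 3 ethanol arrays) and Hoxb2 by 4.18 ± 0.23 (detected on 1 of 3 ethanol arrays). Otx2 fell by 3.05 ± 0.16, Enox1 by 2.99 ± 0.13, Ddx58 by 2.47 ± 0.17 and Zmat4 by 2.39 ± 0.11, and Klk1 was at least 3.28-fold lower. Foxa1 rose by 3.41 ± 0.18, Gata6 by 1.59 ± 0.15 and Meis1 by 2.63 ± 0.12.

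Among the Hox paralogs 1 to 5, 8 of 11 rose (median 3.06, camera adjusted p = 1.35e-15). Among paralogs 6 to 13, 4 rose and 1 fell (median 0.28, adjusted p = 0.00306, and adjusted p = 0.141 with an estimated correlation). Retinoid metabolism genes rose in 4 of 11 cases (median 0.10, adjusted p = 0.00563), with Stra6 at least 5.73-fold and Cyp26a1 at least 4.24-fold higher. The germ cell list had 4 of 9 up (median 0.33, adjusted p = 0.000281, and adjusted p = 0.0771 with an estimated correlation), with Stra8 at 3.02 ± 0.13. The 2-cell-like list, genes of the earliest embryo that flicker on in stem cells, had 3 of 4 measured members up (median 0.96, adjusted p = 0.00236), Zscan4c by 1.06 ± 0.20 (a family of near-identical copies) and Tmem92 at least 1.84-fold. The TALE and Cdx list had 7 of 12 up and 1 down (7 and 2 adjusted over the list alone; median 0.80, adjusted p = 5.67e-06, and adjusted p = 0.0515 with an estimated correlation). FGF-ERK genes had 1 of 14 up and 3 down (1 and 5 adjusted over the list alone; median -0.23, adjusted p = 0.0435). That call was lost with an estimated correlation (adjusted p = 0.1), with median scaling, without knockout ethanol replicate 1 (0.0639) and without knockout 24 h replicate 2 (0.118). Of 28 pluripotency genes, 6 fell and 2 rose (8 and 3 adjusted over the list alone; median -0.16), and the list did not pass (adjusted p = 0.064). With median scaling 498 genes passed, 281 higher and 217 lower, without Zscan4c, and 936 when the groups compared were fitted alone.

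The responses of the 2 lines shared many genes, each line being set against its own ethanol arrays. At 24 h, 600 genes rose in both where independent lists would share 114.1, and 432 fell in both against 72.6. At 8 h the numbers were 210 against 18.9 for rises and 149 against 11.7 for falls, and at 1 h 29 against 0.2 and 2 against 0. Of the 1349 genes raised in wild-type cells at 24 h, 1237 had a positive value in cells labelled knockout, and of the 1062 lowered, 937 had a negative one. Only 12 and 11 of these passed in the opposite direction. The overlap at 24 h was 310 genes with median scaling.

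Before any retinoic acid, the lines differed in 2643 genes, 1365 higher and 1278 lower in cells labelled knockout, 188 and 287 of these by 2-fold or more. The TALE and Cdx list had 4 of 12 members lower and 2 higher (5 and 2 adjusted over the list alone; median -0.14) and did not pass (camera adjusted p = 0.0612, and 0.411 with an estimated correlation). Its member Meis1, a Hox cofactor, differed by -3.02 ± 0.12 (log2, SE, n = 3 per group, adjusted p = 2.49e-13), Meis2 by -1.65, Pknox2 by -1.05 and Tgif1 by 0.64. Its member Cdx2, a regulator of trophoblast and of posterior Hox genes, was at least 5.00-fold lower, with detection on 3 of 3 wild-type and 0 of 3 knockout ethanol arrays. Outside this list, Hoxa5 was at least 3.57-fold lower, and Fgfbp1 (-3.40 ± 0.23, detected on 2 of 3 knockout ethanol arrays), the carbonic anhydrase gene Car4 (-2.98 ± 0.13) and Esam (-2.89 ± 0.15) were also lower. The higher genes were led by the epoxide hydrolase gene Ephx2 (2.43 ± 0.17), Ly6g6e (2.35 ± 0.20), the receptor gene Gpr83 (2.33 ± 0.14), Aff1 (2.31 ± 0.22) and the matrix gene Tgfbi (2.19 ± 0.15). Tgif1 lost its call with median scaling.

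Genes of the pluripotency list were higher in cells labelled knockout under ethanol. Of 28 members 13 were higher and 3 lower (15 and 3 adjusted over the list alone; median 0.36, camera adjusted p = 0.00609), with Nr5a2 at 1.26 ± 0.15, Tcl1 at 1.15 ± 0.10 and Nanog at 0.63 ± 0.09. The 2-cell-like list was higher in 2 of 4 members (3 adjusted over the list alone; median 0.87, adjusted p = 0.0157, and adjusted p = 0.0515 with an estimated correlation). Immediate early genes were lower in 10 of 14 cases (median -0.80, adjusted p = 1.83e-06), including Ccn1 (-1.64 ± 0.16), Ccn2 (-1.51 ± 0.14) and Klf6 (-1.39 ± 0.09). FGF-ERK genes were lower in 7 of 14 and higher in 2 (median -0.33, adjusted p = 0.00295), with the ERK phosphatase gene Dusp4 at -2.42 ± 0.09. Formative genes were lower in 5 of 11 and higher in 1 (6 and 1 adjusted over the list alone; median -0.52, adjusted p = 0.00507), with Pou3f1 at -1.36 ± 0.15. Endoderm genes were lower in 8 of 19 and higher in 1 (median -0.20, adjusted p = 0.00996), with Gata6 at -1.44 ± 0.15. Hox paralogs 1 to 5 were lower in 7 of 11 (median -0.41, adjusted p = 0.00295). Stem cells of this kind can be grown on feeder fibroblasts, and of 5 measured fibroblast markers 1, Fbln2, was lower (adjusted p = 0.452 for the list). With median scaling 803 genes passed, 523 higher and 280 lower, with a median of all genes of 0.18, and the differences of Gata6 and Fbln2 did not pass.

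The difference between the 2 responses was tested directly as an interaction, with negative values for genes that rose less, or fell more, in cells labelled knockout. At 24 h the retinoic acid-binding gene Crabp2 rose by 2.79 in wild-type cells and 0.79 in cells labelled knockout, an interaction of -1.998 ± 0.23 (log2, SE, n = 3 per group, adjusted p = 1.51e-05). In total 290 genes had an interaction at 24 h, 139 positive and 151 negative, 50 and 81 of them by a fitted 2-fold or more. Of the 290, 66 were not detected on any array of at least 1 of the 4 groups compared. The fitted interaction of such a gene rests on the background level, so no size is given for those named here. Hoxa2, a hindbrain gene, rose by 2.90 in wild-type cells (detected on 2 of 3 ethanol arrays) and was at least 1.96-fold higher in cells labelled knockout, where it was not detected under ethanol (interaction adjusted p = 0.000217). The posterior gene Hoxc9 rose by 2.32 in wild-type cells and was not detected in cells labelled knockout (interaction adjusted p = 1.26e-05).

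Other genes with a weaker or opposite response in cells labelled knockout at 24 h were Fgfbp3, an FGF carrier (3.03 in wild-type cells against 0.62), the transcriptional repressor Bach2 (1.48 against -0.85), the immediate early gene Fos (1.15 against -0.82), the cyclin gene Ccnd2 (1.30 against -0.61) and the imprinted gene Mest (1.37 against -0.48). Tmem132e was at least 2.34-fold higher in wild-type cells and was detected at 24 h on 3 of 3 wild-type and 0 of 3 knockout arrays. Rerg, a Ras-related gene, fell more in cells labelled knockout (-0.19 against -2.05). Among positive interactions was Pgbd5, not detected on either set of ethanol arrays, which was at least 3.70-fold higher in cells labelled knockout and was detected at 24 h on 1 of 3 wild-type arrays. Others were the helix-loop-helix gene Tal2 (-0.22 against 1.52), Yipf2 (-0.50 against 1.00) and Tril (0.32 against 1.79), Nphp4, a ciliary gene (0.42 against 1.87), and the cytokine subunit gene Il23a (-0.66 against 0.71). Esam (-1.41 against 0.05), the growth factor gene Hbegf (-1.54 against -0.13) and the lipid phosphatase gene Plpp3 (-0.82 against 0.61) fell in wild-type cells, with no called fall in cells labelled knockout. Enpp2, an enzyme that makes lysophosphatidic acid, was at least 1.5-fold lower in wild-type cells. It was not detected in cells labelled knockout under ethanol or at 24 h, where a fall could not be measured, so its positive interaction follows from the background level. Fgfbp3 was detected on 1 of 3 knockout ethanol arrays, Tal2, Yipf2 and Il23a on 2 of 3, and Bach2 on 2 of 3 wild-type ethanol arrays. Rarg itself had an interaction of 0.84 ± 0.18 (adjusted p = 0.00964). Its second probe, ILMN_3132660, gave 0.49 ± 0.13. Adjusted over all 25697 probes it did not pass (adjusted p = 0.071), where ILMN_2618068 had 0.0125.

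**Figure D3:**
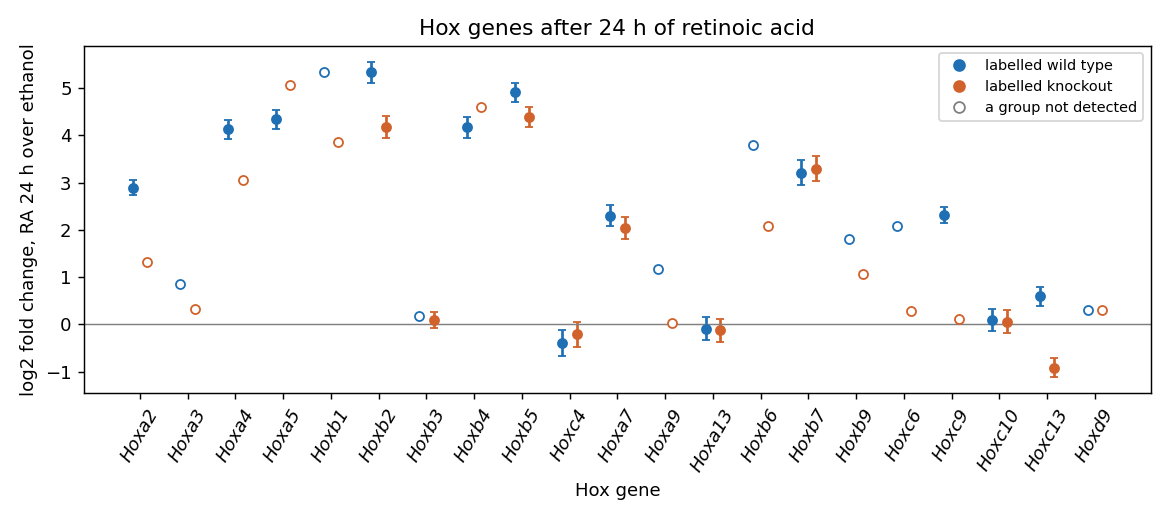
Log2 fold change of measured Hox genes after 24 h of retinoic acid over ethanol, with its standard error, blue for cells labelled wild type and orange for cells labelled knockout. Open circles mark genes not detected on any array of 1 or both groups, whose fitted value is no measured size. Hoxc13 (0.60 against -0.92) lies apart between the lines, while Hoxb7 (3.21 against 3.29) and Hoxa7 (2.30 against 2.04) lie close together.

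Hox paralogs 6 to 13 had a negative interaction as a list at 24 h (median -0.74, camera adjusted p = 9.26e-07). Of 11 members 4 passed the interaction test, and 6 adjusted over the list alone. Beside Hoxc9 these were Hoxc13 (-1.51 ± 0.29), Hoxb6 and Hoxc6. Hoxb6 and Hoxc6 were not detected on any ethanol array, and Hoxc9 not on the knockout ones. The fitted interactions of Hoxb6, Hoxc6 and Hoxc9 therefore rest on the background level, and the list values include them. Hoxb6 was at least 7.22-fold higher in wild-type cells and at least 2.09-fold higher in cells labelled knockout, and Hoxc6 was at least 2.75-fold higher in wild-type cells and not detected in cells labelled knockout. Paralogs 1 to 5 had 4 of 11 members with a negative interaction (median -0.52, adjusted p = 2.78e-05), and 6 negative and 1 positive adjusted over the list alone. Among the 4 were Hoxa2, Hoxa4 and Hoxb1, the last not detected on any ethanol array. Hoxa2 and Hoxa4 were not detected on the knockout ethanol arrays. The rises of all of these in cells labelled knockout are lower bounds, at least 4.64-fold for Hoxa4, so a smaller response was not measured for them. Hoxa4 also lost its call without any 1 of the 12 arrays except knockout ethanol replicate 3 and wild-type ethanol replicates 2 and 3, at adjusted p of up to 0.109. Retinoid metabolism genes responded less as a list (median -0.53, adjusted p = 0.00179) with Crabp2 the 1 member called over all genes and 4 adjusted over the list alone. Wnt and BMP response genes had 5 of 15 members negative and 1 positive (7 and 1 adjusted over the list alone; median -0.32, adjusted p = 0.00472), with Sp5 at -1.34 ± 0.22 and Wnt8a, which rose by 1.80 in wild-type cells and was not detected in cells labelled knockout, and the Wnt deacylase gene Notum at 0.85 ± 0.15.

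Pluripotency genes went the other way. Of 28 members 11 had a positive interaction and 1 a negative one (13 and 1 adjusted over the list alone; median 0.44, adjusted p = 3.53e-09). Zfp42 fell by 1.26 in wild-type cells and gave -0.12 in cells labelled knockout (interaction 1.14 ± 0.23). Esrrb fell by 0.92 and gave -0.16 (0.77 ± 0.14), Eras gave -0.995 and 0.09 (1.09 ± 0.20), and Nanog -0.38 and 0.26 (0.64 ± 0.13). The endoderm list was lower by a median of -0.27 (adjusted p = 0.0215) with 1 of 19 members called, Sox7 (0.97 against 0.07), and 2 adjusted over the list alone. That call was lost with median scaling and without wild-type 24 h replicate 1 (0.0549). The neural list (median -0.42, 2 of 14 members, adjusted p = 0.00252) lost its call at an adjusted p = 0.235 with an estimated correlation and with median scaling. Its member Gap43 lost its call without knockout ethanol replicate 2 (0.0512) or wild-type 24 h replicate 1 (0.0528). The formative list (median -0.28, 2 of 11 members, adjusted p = 0.0281) lost it at an adjusted p = 0.0624 with an estimated correlation, with median scaling, and without knockout ethanol replicate 3 (0.0509), knockout 24 h replicate 3 (0.1), wild-type ethanol replicate 2 (0.0627) or wild-type 24 h replicate 2 (0.0544). Its member Sall2 lost its call without any 1 of the 12 arrays except knockout ethanol replicate 3, knockout 24 h replicate 1 and wild-type ethanol replicates 2 and 3, at adjusted p of up to 0.0933. The immediate early list (median -0.13, 3 of 14 members and 5 adjusted over the list alone, adjusted p = 0.0215) lost it at an adjusted p = 0.0588 with an estimated correlation, and without knockout ethanol replicate 3 (0.106), knockout 24 h replicate 3 (0.0768) or wild-type ethanol replicate 2 (0.0742). Its member Fosb lost its call without knockout ethanol replicate 3 (0.0516), wild-type ethanol replicate 1 (0.0752) or wild-type 24 h replicate 1 (0.0786).

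The 290 interactions at 24 h became 181 without wild-type 24 h replicate 1 and 193 without knockout ethanol replicate 2. With median scaling 41 passed, 4.9% of them positive against 47.9% with quantile normalization, and the median of all genes was -0.39 against -0.02. The pluripotency list then had a median of 0.06 in place of 0.44, so these genes stood above the other genes under both scalings, but whether they fell less depended on the scaling. Under median scaling Crabp2, Hoxc9, Fgfbp3, Bach2, Fos, Ccnd2, Mest, Rerg, Tmem132e, Pgbd5 and Enpp2 kept their calls, and Tal2, Yipf2, Tril, Nphp4, Il23a, Esam, Hbegf, Plpp3, Rarg, Sp5, Notum, Sox7 and the pluripotency genes named here did not.

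**Figure D4:**
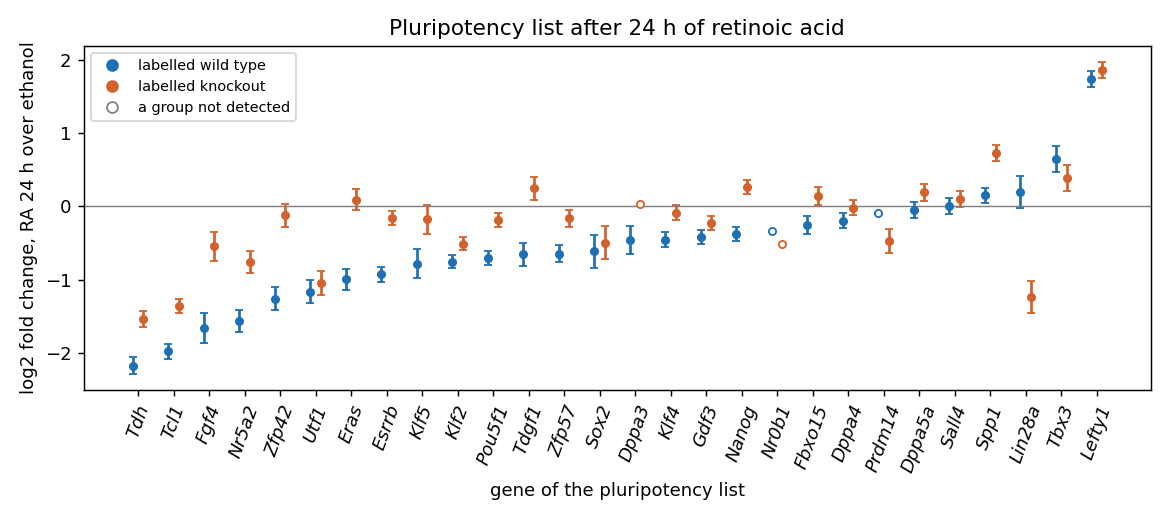
Log2 fold change of each measured gene of the pluripotency list after 24 h of retinoic acid over ethanol, with its standard error, blue for cells labelled wild type and orange for cells labelled knockout, ordered by the wild-type value. Open circles mark genes not detected on any array of 1 or both groups. The list median was -0.53 in wild-type cells and -0.16 in cells labelled knockout.

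Earlier interactions were few and included Hox genes. At 8 h, 5 genes had a positive and 20 a negative interaction. Of these 25, 10 were not detected on any array of at least 1 of the groups compared, and no size is given for those named here. Hoxb1 (adjusted p = 1.82e-09), not detected on either set of ethanol arrays, was at least 5.69-fold higher in wild-type cells at 8 h and was not detected in cells labelled knockout at that time. Hoxb2 had -2.32 ± 0.32. The Hox paralogs 1 to 5 had a negative interaction as a list (median -0.86, camera adjusted p = 6.61e-09). Of 11 members 3 were called, and 6 negative and 1 positive adjusted over the list alone. Id4, which gave 0.56 in wild-type cells (adjusted p = 0.0651) and was at least 2.33-fold lower in cells labelled knockout, had a negative interaction, as did Csn3, not detected on any ethanol array. Positive values were found for Cyp2s1 (1.05 ± 0.20), Cited2 (0.99 ± 0.18) and the urokinase receptor gene Plaur (0.85 ± 0.16). The meiotic kinase gene Aurkc, not detected on any ethanol array, also had a positive one, at least 1.16-fold higher in wild-type cells and at least 3.83-fold in cells labelled knockout. Epha1 passed as well, but it was not detected in cells labelled knockout, where a fall could not be measured, and its second probe gave 0.12.

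At 8 h the retinoid metabolism list (median -0.25, adjusted p = 0.0442), the formative list (median -0.36, adjusted p = 0.0243) and the germ cell list (median -0.32, adjusted p = 0.0215) passed with no member called over all genes and 1, 3 and 2 negative members adjusted over the list alone. They lost their calls at adjusted p = 0.0805, 0.0588 and 0.260 with an estimated correlation, and without single arrays. For retinoid metabolism these were knockout ethanol replicate 3 (0.0685), wild-type ethanol replicates 2 (0.0934) and 3 (0.1), knockout 8 h replicate 3 (0.0714) and wild-type 8 h replicates 1 (0.0704) and 3 (0.0914). For the formative list they were knockout ethanol replicate 1 (0.0504), wild-type ethanol replicate 2 (0.0732), knockout 8 h replicate 3 (0.0738) and wild-type 8 h replicates 1 (0.0573) and 3 (0.0637). For the germ cell list they were knockout ethanol replicate 2 (0.139), wild-type ethanol replicate 1 (0.0576), knockout 8 h replicate 2 (0.0665) and wild-type 8 h replicate 3 (0.052). Hoxb1, Hoxb2, Id4 and Epha1 kept their calls without each array in turn. Cited2 lost its call without knockout 8 h replicate 2 (adjusted p = 0.0555), and Cyp2s1 without that array (0.0531), knockout ethanol replicate 2 (0.0643), knockout 8 h replicate 3 (0.0518) or wild-type ethanol replicate 1 (0.0514). Plaur lost it without knockout ethanol replicate 1 (0.0694) or 2 (0.0568), knockout 8 h replicate 2 (0.0683) or 3 (0.0672), wild-type ethanol replicate 1 (0.0642) or wild-type 8 h replicate 1 (0.0629). Aurkc lost it without knockout ethanol replicate 1 (0.0602) or 2 (0.0905), knockout 8 h replicate 1 (0.0777) or 2 (0.0961), wild-type ethanol replicate 1 (0.0564) or 3 (0.0906) or wild-type 8 h replicate 1 (0.0509). Csn3 lost it without any 1 of the 12 arrays except knockout 8 h replicate 1 and wild-type 8 h replicate 2, at adjusted p of up to 0.114. The 25 calls became 40 without wild-type 8 h replicate 2 and 14 without knockout 8 h replicate 2, and with median scaling 1 passed, Hoxb1.

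At 1 h the interaction of Hoxb1 passed (adjusted p = 0.0264). The gene was not detected under ethanol or in cells labelled knockout at 1 h and was at least 1.31-fold higher in wild-type cells. No other of the 10432 genes did, with 247 at an unadjusted p under 0.05. The 1 call became 0 by limma without any 1 of the 12 arrays except wild-type 1 h replicate 1, at adjusted p of up to 0.157. It also became 0 with median scaling, no background correction, the replicate block and a fit of the groups compared alone. The authors' value table gave 0 too, being the values without background correction, centred. As a list, Hox paralogs 1 to 5 had a negative interaction (median -0.46, camera adjusted p = 1.83e-06, 1 of 11 called and 4 adjusted over the list alone).

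Among the lists without a call in any of the 10 comparisons were primitive streak and mesoderm (8 measured), trophoblast (10), fibroblast markers (5), Polycomb complexes (16), DNA methylation machinery (9), cell cycle (21) and p53 and apoptosis (16). In wild-type cells at 24 h their camera adjusted p were 0.829, 0.0989, 0.858, 0.775, 0.389, 0.802 and 0.733. Single members did move: in the DNA methylation list at 24 h Dnmt3l fell by 0.70 ± 0.10 in wild-type cells and by 1.21 ± 0.10 in cells labelled knockout. In the cell cycle list Ccnd1 fell by 1.20 ± 0.16 in cells labelled knockout.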

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

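The interaction tests, the list tests and the setting with median scaling were planned. The tests on other splits, on the first principal component, on the detection of Rarg and of collagens, on imprinted genes, with brightness as a covariate and without the 2 dimmest arrays were chosen after the results were seen, and so was the use of the list values as tests of the pluripotency pattern. Each result below is a difference between the lines in the response to retinoic acid, given as the interaction on the log2 scale (n = 3 arrays per group). For genes not detected on any array of a group compared, 1 of 1 at 1 h, 10 of 25 at 8 h and 66 of 290 at 24 h, the value is a fitted one that rests on the background level and is no measured size. Of those named these are Hoxb1, Epha1, Aurkc, Id4 and Csn3, and at 24 h Pgbd5, Enpp2, Tmem132e and Hoxc9. Epha1 and Enpp2 could not fall from the background in cells labelled knockout.

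At 1 h the test found 1 gene, Hoxb1 (-0.995), and the list of Hox paralogs 1 to 5 moved by a median of -0.464. At 8 h it found 25 genes. Among these, Epha1 had 1.174, Aurkc 1.099, Cyp2s1 1.047, Cited2 0.994, Plaur 0.847, Id4 -1.921, Csn3 -1.967, Hoxb2 -2.316 and Hoxb1 -2.631. List medians at 8 h were -0.246 for retinoid metabolism and transport, -0.858 for Hox paralogs 1 to 5, -0.356 for the formative and primed state and -0.324 for germ cell and meiosis genes.

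At 24 h the test found 290 genes. Those responding more positively in cells labelled knockout included Pgbd5 (1.99), Tal2 (1.738), Yipf2 (1.493), Tril (1.471), Esam (1.465), Nphp4 (1.448), Plpp3 (1.427), Hbegf (1.418), Enpp2 (1.393), Il23a (1.371) and Rarg (0.838). The more negative included Mest (-1.848), Tmem132e (-1.861), Rerg (-1.863), Ccnd2 (-1.91), Fos (-1.967), Crabp2 (-1.998), Hoxc9 (-2.209), Bach2 (-2.336) and Fgfbp3 (-2.416). List medians at 24 h were -0.529 for retinoid metabolism and transport, -0.522 for Hox paralogs 1 to 5, -0.737 for Hox paralogs 6 to 13, 0.44 for pluripotency, -0.278 for the formative and primed state, -0.27 for endoderm, -0.419 for neural genes, -0.134 for immediate early genes and -0.317 for Wnt and BMP response genes.

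Other splits of the same arrays were counted for each comparison. Each comparison of retinoic acid with ethanol, and of the lines under ethanol, has 10 splits of 6 arrays, too few for a share under 0.05, and 1 split, the real one, gave as many genes in each. The real counts and the highest of the other splits were 72 and 0, 1023 and 2, and 2411 and 0 for wild-type cells at 1, 8 and 24 h, 43 and 0, 621 and 1, and 1595 and 0 for cells labelled knockout, and 2643 and 4 between the lines. For the interactions the averages of line and treatment were removed before the arrays were split. For the interaction at 1 h, 5 of 100 splits gave at least the 1 gene found, with a highest other of 74, so chance was not excluded. For the interaction at 8 h, 2 of 100 splits, the real one included, gave at least 25 genes, a share under 0.05. The highest other split gave 1524, many times the real count, for a reason that was not tested. For the interaction at 24 h, 2 of 100 gave at least 290, also under 0.05, with a highest other of 355. These splits mixed arrays of all groups compared, so any interaction added to the spread within them. Another split gave more genes than the real one at both times, so the share by itself does not exclude chance.

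Rarg was detected on 12 of the 12 knockout arrays. Arrays swapped between the lines would lie on the other line's side of the first principal component, and 0 did. Whether the label refers to a deleted regulatory element or to a Rarg deletion that leaves the probed part of the transcript cannot be told apart, because both may leave Rarg detected on 12 arrays.

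The lines differed in 2643 genes before treatment. The ethanol arrays overlapped in mean intensity, 351.7 to 997.3 in wild-type cells and 535.1 to 1403.3 in cells labelled knockout. With brightness as a covariate 2599 of the genes stayed called, which argues against a linear effect of brightness as the whole cause. With median scaling 784 stayed called, so the size of the difference depended on the scaling. The collagens Col1a1, Col1a2 and Col3a1, abundant in fibroblasts, had 0 detections on the ethanol arrays. That goes against a large share of feeder fibroblasts only if these probes work. They had 0 detections on the other arrays too, so no array here shows that they do. Of 20 measured imprinted genes, whose level can drift between stem cell lines in culture, 14 differed. That was more than in any of 10000 random lists matched on level (median 5, highest 13). The random genes were drawn independently, so the comparison makes no allowance for imprinted genes that change together. With median scaling 8 differed, and no random lists were drawn for it. A separate history of the lines and the genotype itself cannot be told apart, because each line is 1 genotype.

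Pluripotency genes fell less in cells labelled knockout at 24 h with quantile normalization. Without the 2 dimmest arrays the list test still passed (adjusted p = 2.09e-08, median 0.432). Of these, wild-type ethanol replicate 1 is part of this comparison and wild-type 8 h replicate 2 is not. Dim knockout arrays stayed in, with mean intensities of 487.3 for 24 h replicate 2 and 535.1 for ethanol replicate 3. The values therefore argue only against that wild-type ethanol array as the whole cause. The scaling of the arrays stays open: with median scaling the list had a median of 0.064 in place of 0.44 and all genes -0.385, and the list test (adjusted p = 9.19e-05) sets the list against other genes, so a shift of all genes alike cannot end it. Median scaling aligned the median of all probes, of which 47.9% to 50.7% were detected on each array, so that median lay near the background. Whether it removed differences in brightness between the arrays was not tested. The list stood 0.356 higher under ethanol in cells labelled knockout, and the same ethanol arrays enter both values. Scaling, a different starting level and a different response cannot be told apart on these arrays, and each may underlie the pattern.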

How the results depend on the processing

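The settings without the 2 dimmest arrays and with brightness as a covariate were chosen after seeing the data. Of 485 gene results, 0 reversed under the settings they were run under. With the stricter filter 475 were run, and leave-one-out covered the arrays compared. A reversal was not possible under several settings. With only the groups compared, the replicate block or all probes, the fold change of the probe tested stayed as reported. The filters on detection kept the same normalized values. Other kept probes were no part of this count. Of the 120 largest changes, 21 had some, and for 1 another probe had the opposite sign. Of the 485, calls were lost for 215 with median scaling, 100 with only the groups compared fitted and 24 without the 2 dimmest arrays. The replicate block lost 18 and each other setting that kept all arrays at most 13, while array weights added 3. Leaving out 1 array at a time ended the call in 359 of 3306 gene runs and 35 of 450 list runs. Each run is 1 result without 1 array, so a result enters once for each array left out. Of 61 list results, 8 were lost with median scaling and 6 with only the groups compared. The cause was not tested, except that a fit on fewer arrays has fewer residual degrees of freedom.

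With median scaling, retinoic acid at 1, 8 and 24 h gave 10, 109 and 1032 genes in wild-type cells and 7, 130 and 498 in cells labelled knockout, the lines differed in 803 under ethanol, and the interactions gave 0, 1 and 41. The median of all genes was then 0.109, 0.053 and 0.252 in wild-type cells, 0.119, 0.026 and -0.095 in cells labelled knockout, 0.176 between the lines, and 0, -0.03 and -0.385 in the interactions, and lay between -0.024 and 0.005 in the fit reported. With only the groups compared, wild-type cells gave 23 genes at 1 h and 151 at 8 h, cells labelled knockout 10 at 1 h and 936 at 24 h, and the interaction at 1 h 0. That interaction also gave 0 with no background correction and with the replicate block. The authors' value table gave the same counts as no background correction, because the values differ only by centring, and is no separate setting. By limma, 247 genes had an unadjusted p under 0.05 for it in the fit reported.

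Array weights gave 1174, 6523 and 5327 genes in wild-type cells, 728, 2328 and 6050 in cells labelled knockout, 5703 between the lines, and 166, 3613 and 4092 for the interactions. The estimate of the weights did not converge, and they ran from 0.0509 to 35.8 within the wild-type 8 h group. Without the 2 dimmest arrays, wild-type cells at 8 h gave 547 genes and cells labelled knockout at 1 h 82. With brightness as a covariate, wild-type cells gave 161 at 1 h and 1720 at 8 h, cells labelled knockout 88 and 948, and the interaction at 8 h 60. The overlap of the lines at 24 h was 310 genes with median scaling, 665 with only the groups compared and 2986 with array weights. The difference of Rarg under ethanol was -0.258 with median scaling.

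Leaving out each array in turn gave 47 to 54 genes in wild-type cells at 1 h and 546 to 1225 at 8 h, 27 to 42 in cells labelled knockout at 1 h, and 0 to 1, 14 to 40 and 181 to 381 for the interactions. The replicate numbers showed no pairing of the arrays on average. Residuals of arrays with the same number had a mean correlation of -0.043 over 84 pairs, against 0.024 over 168 pairs with different numbers. These means are tied, because the residuals of a group sum to 0. Single pairs ran from -0.491 to 0.473 with the same number and from -0.514 to 0.54 with different ones. Pairing between some of the groups was not excluded. With the replicate block the counts were 63, 842 and 2220 in wild-type cells, 37, 565 and 1486 in cells labelled knockout, 2452 between the lines, and 0, 23 and 244 for the interactions. No slide was given for any array, so a slide block was not run. Signal over background limits dim genes, whose fold changes are compressed.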

Other observations

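Imprinted genes, which are expressed from 1 parental copy and can lose that control in cultured stem cells, were looked at after the difference between the lines was seen. Of 20 measured, 12 were lower and 2 higher in cells labelled knockout under ethanol. The 14 calls became 8 with median scaling, 11 with only the groups compared fitted, 18 with array weights and 11 to 14 without 1 array. Peg10, a placental retrotransposon-derived gene, was lower by -2.80 ± 0.17 (log2, SE, n = 3 per group), and the growth factor gene Igf2 by -2.18 ± 0.14. The noncoding RNA gene H19 was at least 3.69-fold and Nnat at least 2.61-fold lower, each detected on 3 of 3 wild-type and 0 of 3 knockout ethanol arrays. Dlk1, a Notch ligand relative, was lower by -1.38 ± 0.21, the cell cycle inhibitor gene Cdkn1c by -1.27 ± 0.20 and Mest by -0.96 ± 0.14. Grb10, a growth factor receptor adaptor gene, was higher by 1.58 ± 0.11, and Phlda2 by 0.52 ± 0.18.

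Of the 476 genes that changed 2-fold or more in wild-type cells at 24 h, 459 moved the same way in cells labelled knockout, by a median share of 0.63 of the wild-type log2 change. This share was computed after the results were seen. It was 0.51 with median scaling, 0.71 with brightness as a covariate and 0.57 to 0.68 without 1 array, each on the genes that changed 2-fold under that setting. The genes were picked by their wild-type values, which lowers such a share.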
